A study of Mus musculus with 8 samples.

How the data were processed

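Genomic DNA of mouse embryonic stem cells, Tdg knockout or Tdg floxed, was sonicated and immunoprecipitated with antiserum against 5fC or 5caC, per the labels' protocols. The captured DNA then went either straight to bisulfite or first through a protecting reaction, with O-ethylhydroxylamine for 5fC and a carbodiimide-coupled amine for 5caC, per the labels' protocols. Libraries were made from bisulfite-treated DNA and sequenced. The submitters' processing notes name Bismark, HOMER and the mm9 build, without saying which step each served. Positions are printed as the files give them.

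The authors deposited 1 list of cytosines per mark for the knockout, with 4 read counts per cytosine (C and T reads in the protected and in the bisulfite-only library, per the file headers), a difference and a p-value. The counts are whole reads with no normalization. The deposited difference equals the protected minus the bisulfite-only fraction of C reads, within 0.0001 at all 7213 and 4806 sites. The deposited p-value equals an unadjusted two-sided Fisher's exact test of the 4 counts, within 1% at all sites. As the values show, listed sites had at least 10 reads in each library, a difference above 0 and a p below 0.05. Whether copied reads were removed is not given in the sources used here. No molecular identifiers are mentioned, so reads may not be independent molecules, and single-site intervals and limits cover counting error only. The listing rule keeps upward chance deviations, so listed levels are biased upward, most at low depth.

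Read columns were assigned to the 2 knockout libraries of each mark by their names, the file's mark and genotype, and the sample titles. Each group had 1 library, so nothing was averaged and no spread between samples exists. The level of a site is the difference of unconverted percentages in percentage points. Medians over sites carry 95% intervals from 1000 bootstrap resamples of blocks of 1000000 bp. Shares of sites and single-site percentages carry exact (Clopper-Pearson) 95% binomial intervals, and a count of 0 is given with the limit of 3 counts of its total. Intervals of shares treat sites as independent, so they are too narrow where sites lie close together. Reads at listed sites ranged from 10 to 7198 per library for 5fC and from 10 to 37985 for 5caC, and 78.4% of 5fC and 83.8% of 5caC sites had under 20 reads in at least one library.

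The expectation under equal levels was computed per site from the hypergeometric distribution of its table, conditional on the 4 margins and on being listed. For shared cytosines, bisulfite-only reads at an assumed level were drawn 1000 times from a binomial distribution, given the observed protected reads and the listing rule. Sharing between lists was compared with 1000 circular shifts per chromosome and with 1000 sets of random moves of up to 50000 bp. Grouping was compared with 1000 sets of uniform positions, since no genome was used to draw CpGs from. Sites within 200 bp were joined into groups. A CpG listed on both strands is a plus-strand site with a minus-strand site 1 bp on. A planned comparison of strands by random strand assignment could not be made, because the lists hold no unlisted partners, so these counts have no chance level. Chromosome lengths were replaced by the span of listed positions. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

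The method was tested on simulated data with the depths of each list, 62000 sites of which 2000 were changed. For the 5fC depths, 157 unchanged listed sites had p below 0.01 against 149 expected, and 82.9% of sites changed by 50 percentage points were listed. For the 5caC depths these were 120 against 132, and 80.8%. The upper limit on unchanged sites came to 61.8% where the true share was 35.8%, and to 62.9% where it was 36.3%.

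The per-site test, the comparisons of levels, sharing, strands, groups and chromosomes, and the rule for named sites, were fixed before the data were examined. The expectation under equal levels, the depth classes, the bisulfite-only and paired comparisons with their drawn reads, the expected noise among shared sites, the count of groups per chromosome, the partner-cytosine counts, the last Mb of X and the sites of lowest p were chosen after values had been seen. The rule names, per mark, the 10 sites with the highest level at 10 or more reads per library, the 10 shared sites with the highest smaller level and the 5 groups with the most sites, of which examples are printed. Gene lists fixed beforehand (pluripotency, DNA methylation and demethylation, imprinted, germline, early embryo, Polycomb targets and complexes, housekeeping, neural and fibroblast genes) could not be applied. The reference table at hand is of another build (GRCm38.p6), so no gene was assigned to a position. For the same reason genomic features and sequence context were not analysed here. The floxed libraries were not analysed here either.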

Results

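The series profiled 2 oxidised forms of cytosine, 5-formylcytosine (5fC) and 5-carboxylcytosine (5caC), in mouse embryonic stem cells. TET enzymes make these bases from 5-methylcytosine (5mC) by way of 5-hydroxymethylcytosine (5hmC), and the glycosylase TDG cuts them out of DNA. The 8 samples are 1 library each of 8 groups, defined by the genotype (Tdg knockout or Tdg floxed), the antibody (anti-5fC or anti-5caC) and the treatment. One treatment was ordinary bisulfite, under which 5mC and 5hmC read as C while cytosine, 5fC and 5caC read as T. The other was bisulfite after a chemical protection that keeps the immunoprecipitated base, 5fC or 5caC, reading as C. The rise of unconverted reads with protection is therefore the measured level of the mark. This level refers to DNA captured by the antibody, not to all copies of a cytosine in the cells. It also depends on the yield of the protection, which is not given here. The values analysed come from the 4 knockout libraries, as a list of 7213 cytosines for 5fC and a list of 4806 cytosines for 5caC, both on the mm9 build. At the listed cytosines the 5fC libraries held 228483 reads with protection and 177260 without, and the 5caC libraries held 161420 and 127094. The median cytosine had 19 protected and 14 bisulfite-only reads on the 5fC list, and 20 and 13 on the 5caC list. There were no replicate libraries, so the tests compare the reads of 2 libraries. Intervals cover counting error at single sites or spread over sites, not the spread between libraries.

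The first comparison asked at which single cytosines protection of 5fC raised the share of unconverted reads in knockout cells. The median listed cytosine went from 40% unconverted reads with bisulfite alone (95% block bootstrap interval 40 to 41.7) to 85.7% with protection (85.0 to 86.4). The median difference was 40.6 percentage points (40 to 41.2), with quartiles of 32.5 and 49.2. Before protection 2867 of the 7213 cytosines (39.7%, exact 95% interval 38.6 to 40.9) already read as C in at least 50% of reads, and 307 (4.26%) had no unconverted read. With protection 1496 cytosines (20.7%) had no converted read. The 10 cytosines with the highest 5fC level lay on 7 chromosomes and differed by 85.7 to 100 percentage points between libraries. The highest was position 53937962 of chromosome 6, plus strand, where 17 of 17 protected reads were unconverted (exact 95% interval 80.5 to 100%) against 0 of 10 without protection, which allows a share of up to 30%. On the minus strand of chromosome 2, position 124990125 read as C in 16 of 16 protected reads and 1 of 11 bisulfite-only reads. Position 37761063 of chromosome 19, minus strand, gave 13 of 15 protected and 0 of 13 bisulfite-only reads. By Fisher's exact test, two-sided, these 10 sites had unadjusted p-values between 1.19e-07 and 0.000119.

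Each site of both lists had an unadjusted p below 0.05, a higher level with protection and at least 10 reads in each library, so a Benjamini-Hochberg adjustment over a list alone passed all 7213 and all 4806 sites and carries no further information. The number of cytosines tested before listing is not given in the sources used here. Bonferroni over the list was met by 21 5fC and 50 5caC cytosines. It also counts listed sites only, so it does not correct for all cytosines tested.

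**Figure D1:**
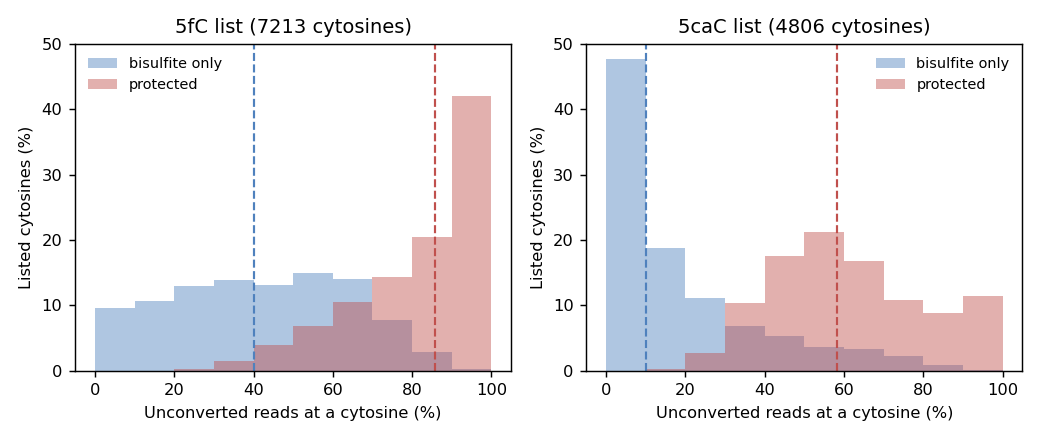
Distribution of the percentage of unconverted reads per listed cytosine (x axis) as the percentage of listed cytosines (y axis), for the 5fC list (left) and the 5caC list (right). Blue is bisulfite only and red is protected, in classes of 10 percentage points, and dashed lines are medians: 40% and 85.7% for 5fC, 10.0% and 58.3% for 5caC.

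The second comparison asked the same of 5caC. The median listed cytosine went from 10.0% unconverted reads with bisulfite alone (interval 10.0 to 10.0, since read numbers are small) to 58.3% with protection (57.7 to 59.1). The median difference was 42.9 percentage points (42.2 to 43.3), with quartiles of 35.7 and 50.0. No unconverted read was present before protection at 1355 of the 4806 cytosines (28.2%, exact 95% interval 26.9 to 29.5), and 490 (10.2%) already read as C in at least 50% of reads. With protection 261 cytosines (5.43%) had no converted read. The 10 cytosines with the highest 5caC level lay on 7 chromosomes and differed by 82.3 to 100 percentage points. Position 12187108 of chromosome 18, minus strand, was unconverted in 13 of 13 protected reads (exact interval 75.3 to 100%) and in 0 of 10 bisulfite-only reads, which allows up to 30%. Position 118639571 of chromosome 5, plus strand, gave 15 of 15 protected and 1 of 15 bisulfite-only reads. Position 70246313 of chromosome 9, minus strand, gave 13 of 14 and 0 of 14. The unadjusted p-values of these 10 sites, two-sided by Fisher's exact test, ran from 2.06e-07 to 0.000119. The smallest p of the list, 3.23e-23 by the same Fisher's exact test, was at position 74917322 of chromosome 15, plus strand, a site chosen after its values were seen. It read as C in 210 of 409 protected reads (51.3%) and 56 of 332 bisulfite-only reads (16.9%).

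Depth set the smallest level that could be listed. On the 5fC list, cytosines with 20 to 25 reads over both libraries had a median difference of 50.0 percentage points, while those with over 200 reads had 10.1. The corresponding 5caC medians were 50.0 and 8.78. Given each site's read totals, the lowest difference that the rule could list had a median of 38.3 percentage points for 5fC and 40 for 5caC, and 75.1% of 5fC and 74.4% of 5caC cytosines stood exactly at it, against 89.6% and 91.2% expected with equal levels. Cytosines with at least 100 reads in each library (126 for 5fC, 27 for 5caC) had median differences of 9.41 and 8.50 percentage points, and held 30.4% and 35.9% of the reads at listed sites. At one of them, position 98507248 of chromosome 2, plus strand, protected and bisulfite-only 5caC libraries differed by 1.88 percentage points over 27944 and 37985 reads, with a Fisher's exact p of 4.9e-19. Whether the reads at this position come from a single place in the genome was not tested.

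**Figure D2:**
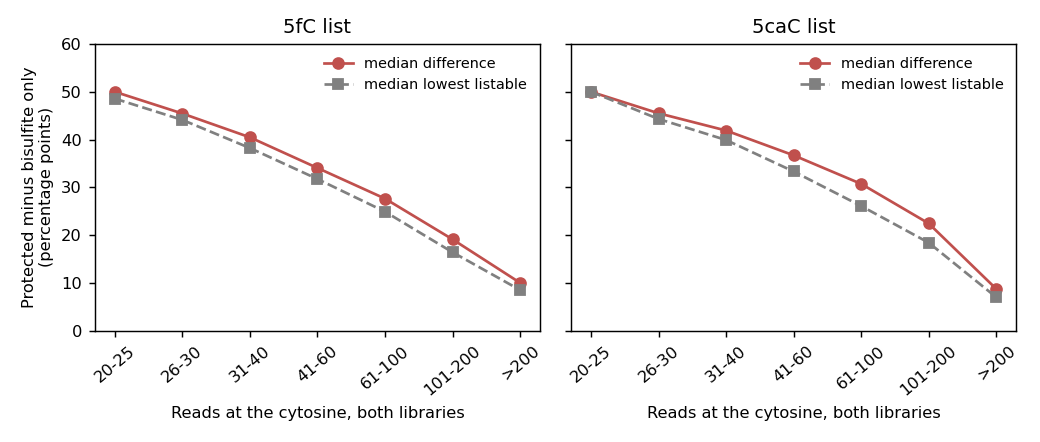
Median difference between protected and bisulfite-only unconverted reads in percentage points (y axis, red) by the number of reads at the cytosine over both libraries (x axis, classes), for 5fC (left) and 5caC (right). Grey squares are the median of the lowest difference that could be listed at each cytosine's read totals, and the red line runs at or a few points above it.

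The lists also differed from what equal levels in the protected and bisulfite-only libraries would give. If no listed cytosine had changed, the exact hypergeometric distribution given each site's read totals and the listing rule puts 1451 ± 22.9 (SD) 5fC cytosines at p below 0.01, and 2440 were there. For 5caC the expectation was 1011 ± 17.8 and 1737 were observed. If reads are independent molecules, the count of sites at p of 0.03 or more limits the share of unchanged cytosines. At most 81.5% of the 5fC list (interval 78.7 to 84.4) and 79.9% of the 5caC list (76.3 to 83.6) could then be unchanged. This is an upper limit under that assumption, since changed cytosines also fall in that range. Copied reads or uneven conversion could move unchanged cytosines to smaller p, and the limit would then not hold.

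**Figure D3:**
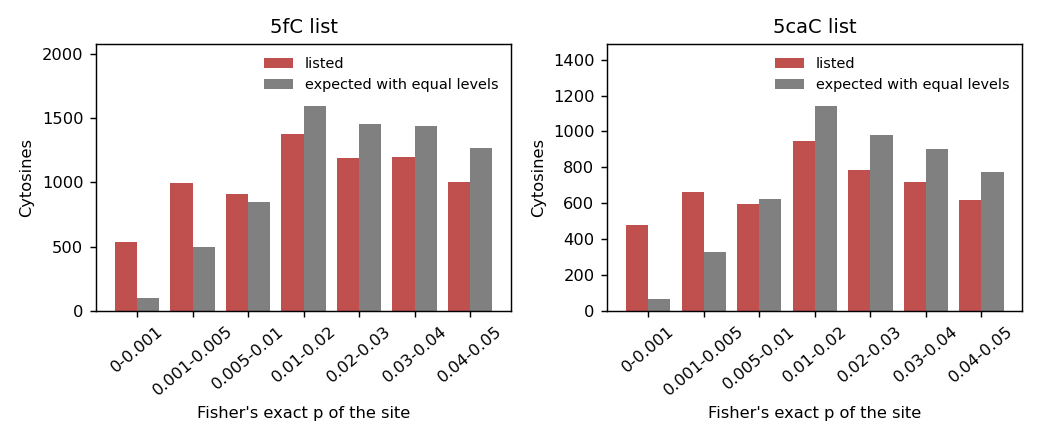
Number of listed cytosines (y axis) by the site's p from Fisher's exact test (x axis, unequal classes), for 5fC (left) and 5caC (right). Red bars are the listed sites and grey bars the number expected with equal levels in both libraries. Below 0.001 there were 534 5fC sites against 103 expected, and 479 5caC sites against 63.6.

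Next, the levels of the 2 lists were set side by side. The 5fC cytosines carried far more unconverted reads before protection than the 5caC cytosines, by 30 percentage points in the median (interval 30 to 31.7), and were 27.4 points higher with protection (26.4 to 28.6). At the 139 5fC and 31 5caC sites with over 200 reads in both libraries together, the difference before protection was -3.12 points (-10.8 to 53.9). The rise with protection differed little, by -2.30 points for 5fC minus 5caC (-2.86 to -1.37). The lowest listable differences already differed by -1.67 points (-2.22 to -1.09), and among sites with p below 0.005 the sign turned, to 0.51 points with an interval including 0 (-1.25 to 1.59). Antibody, protection chemistry and read depth all differed between these libraries, and cytosines are not replicates, so no p is given. At the 314 cytosines on both lists the bisulfite-only level was higher in the 5fC library at 223 cytosines and lower at 77, with a median paired difference of 8.33 points (6.38 to 10.0). The listing rule alone, with equal bisulfite-only levels, gives 2.40 to 7.32 points there, depending on the level assumed. The higher value assumes no rise with protection at any shared cytosine.

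A further comparison asked whether 5fC and 5caC were listed at the same cytosines. Of the 7213 5fC cytosines, 314 (4.35%, exact 95% interval 3.89 to 4.85) were also 5caC cytosines on the same strand, which is 6.53% of the 5caC list. Circular shifts of the 5caC sites along each chromosome gave a mean of 0.009 shared sites and never more than 1 in 1000 shifts (permutation p = 0.001, one-sided, the smallest that 1000 shifts can give). Moving each 5caC site at random by up to 50000 bp gave a mean of 0.056. Neither keeps sites on CpGs or in immunoprecipitated regions, so both understate chance sharing. If all 7213 cytosines had enough 5caC reads and equal levels, listing by noise at the mean chance of 5caC sites would give 136 shared cytosines, and 353 at the highest chance. In wider windows 1088 5fC cytosines (15.1%) had a 5caC cytosine within 100 bp and 1671 (23.2%) within 1000 bp, with means of 3.21 and 29.2 after circular shifts, and of 18.5 and 177 after moves of up to 50000 bp. The shared cytosine with the highest smaller level was position 115919694 of chromosome 11, minus strand. There 15 of 16 reads were unconverted with 5fC protection and 18 of 26 with 5caC protection, against 0 of 10 and 0 of 11 with bisulfite alone. At position 65536253 of chromosome 5, plus strand, the level was 63.1 percentage points for 5fC and 60.4 for 5caC, and at position 178048399 of chromosome 2, plus strand, 61.6 and 57.9. Position 64204640 of chromosome 10, minus strand, gave 58.6 and 57.6. The 10 shared sites chosen by this rule lay on 7 chromosomes, with levels of 53.6 to 93.8 points for 5fC and 53.3 to 69.2 for 5caC.

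Both marks were listed on 1 strand of a CpG far more often than on both. In total 32 CpGs had both cytosines on the 5fC list, which is 0.446% (exact 95% interval 0.305 to 0.629) of the 7181 CpGs listed if each site is a CpG. For 5caC it was 41 of 4765, or 0.860% (0.618 to 1.17). The partner cytosine of 52 5fC sites was on the 5caC list, against 314 for the same cytosine. Plus and minus strands were listed alike, with 3644 and 3569 5fC sites (binomial test, two-sided, p = 0.384) and 2428 and 2378 5caC sites (binomial p = 0.480). An unlisted partner is not shown to be unmodified, since its reads are not in the lists and it may not have reached 10 reads.

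Listed cytosines lay in groups. Another 5fC site was within 200 bp of 2755 5fC cytosines (38.2%, exact interval 37.1 to 39.3) and another 5caC site within 200 bp of 1722 5caC cytosines (35.8%, 34.5 to 37.2). Uniform random positions on the same chromosomes gave means of 0.237% and 0.0855% (permutation p = 0.001 for each, one-sided, the smallest possible with 1000 draws). This background ignores where CpGs and immunoprecipitated reads lie. The group with the most 5fC cytosines held 20 over 980 bp of chromosome 17, from 39981795 to 39982774. Together with 2 further groups at 39984572 to 39985022 and 39985482 to 39985671, of 13 and 12 sites, it makes up 3 of the 5 largest, and none of the 3 held a 5caC site. Their median levels were low, 11.6 to 15.2 percentage points. Median depths were 102.5 to 213.5 protected reads, against 19 over the whole 5fC list. Cytosines there that are missing from the 5caC list are not shown to lack 5caC. A group of 18 5fC cytosines on chromosome 11, from 3093001 to 3093487, had a median level of 9.87 points and contained 6 5caC sites. Its median depth was 262.5 protected reads. Whether the deep positions of these groups each stand for a single place in the genome was not tested. The largest 5caC group had 7 cytosines over 230 bp of chromosome 11, from 59063288 to 59063517, with a median level of 47.9 points and 19 protected reads. A group of 6 on chromosome 2, from 169041327 to 169041436, had a median 5caC level of 34.4 points and contained 4 5fC sites. Another 6 within 41 bp of chromosome 3, from 9614922 to 9614962, had a median level of 29.5 points and a bisulfite-only level of 3.57%. Leaving out cytosines with at least 100 reads in each library left 37.4% of 5fC and 35.7% of 5caC cytosines with a neighbour.

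Along the chromosomes, both lists were sparse on X. The autosomes held 2.98 5fC and 2.00 5caC cytosines per Mb, and X held 0.448 and 0.151, with Mb counted between the first and last listed positions of a chromosome. X made up 6.22% of this length and held 71 of 7213 5fC sites (0.984%, exact interval 0.770 to 1.24) and 24 of 4806 5caC sites (0.499%, 0.320 to 0.742). Of these, 30 5fC and 18 5caC sites lay in the last Mb, from 165442486 to 166442485, where median depth was 54.5 and 44.5 protected reads. The rest of X held 41 5fC and 6 5caC cytosines. Median depth there was 22 protected and 15 bisulfite-only reads for 5fC. For 5caC it was 11.5 and 12, near the 10 reads that listing needed. Reads at unlisted cytosines are not in the lists, so low coverage of X was not tested as a cause. The most 5fC sites per Mb were on chromosome 17 (4.58), though with groups counted once chromosome 11 came first (3.25 against 3.13), and the most 5caC sites per Mb on chromosome 19 (3.21). Neighbouring sites are not independent, so intervals of these shares are too narrow.

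**Figure D4:**
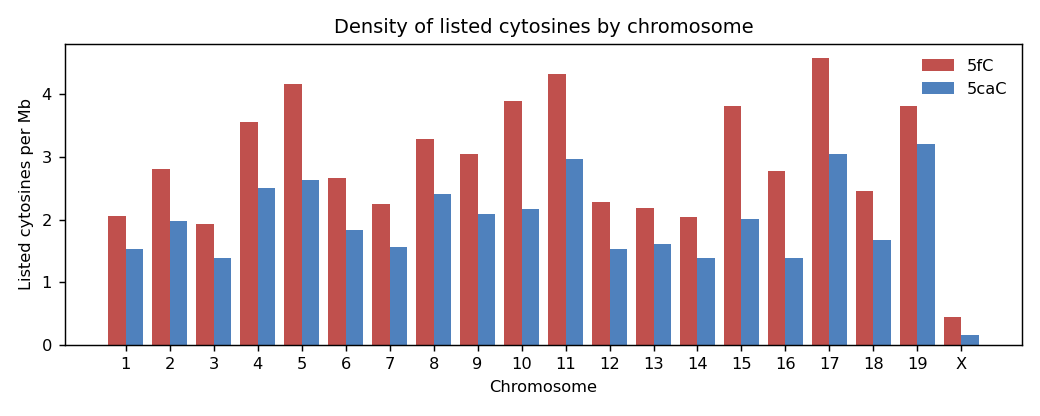
Listed cytosines per Mb (y axis) by chromosome (x axis) for 5fC (red) and 5caC (blue). Bars for X stand at 0.448 and 0.151, below every autosome, of which the lowest are 1.92 and 1.38.

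The floxed libraries were not analysed here, so no comparison of knockout with floxed cells is made. No mm9 genome or annotation was used here, so the sites are given by position, without genes, exons, promoters or sequence context.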

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

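The settings that leave out sites with at least 100 reads in each library, use p below 0.001 (or 0.005 for the difference between lists), take 1 site per group, cut the last Mb of X or recompute the bisulfite-only comparison were added after seeing the data. With an adjusted p below 0.01 over the list, 313 5fC and 479 5caC sites passed. This adjustment counts listed sites only, so passing it does not correct for all cytosines tested. With at least 20 reads in each library 1561 and 777 sites were left, as fewer sites reach that depth. A minimum of 10 reads removed no site, so that setting tests nothing. The median 5fC level was 28.1 percentage points at 20 or more reads, 53.8 for p below 0.005 and 59.1 for p below 0.001, and the 5caC median was 31.2, 53.3 and 57.1: the depth and p limits set these medians. The 5fC minus 5caC difference of median levels was -3.16 points at 20 or more reads, -2.16 on autosomes and -1.95 without the deepest sites, with intervals below 0, but turned to 0.51 (-1.25 to 1.59) for p below 0.005 and 1.99 (-0.67 to 3.81) for p below 0.001, so its direction is not stable. The bisulfite-only difference was 21.2 points for p below 0.001 and 39.4 at 20 or more reads, but -3.12 (-10.8 to 53.9) at the few sites with over 200 reads in both libraries together. Sharing counted as the same CpG on either strand gave 355 5fC sites, within 100 bp 1088 and within 1 kb 1671. It was 309 without the deepest sites and 293 counting each 200 bp group once. CpGs listed on both strands numbered 27 for 5fC and 41 for 5caC without the deepest sites. The share of sites with a neighbour was 33.4% within 100 bp and 45.4% within 1 kb for 5fC, and 30.9% and 42.5% for 5caC, by construction of the window. The highest chromosome density was 10.2 times the lowest for 5fC and 21.2 times for 5caC. Counting each 200 bp group once gave 11.0 and 20.5. The ratios fell to 2.38 and 2.32 on autosomes alone and rose to 17.6 and 84.4 with the last Mb of X left out. The last 2 ratios rest on the 41 5fC and 6 5caC sites left on X. All these ratios are per Mb, not per cytosine with enough reads. Of 46 named-site values (a site named under 2 rules counts each time), 16 no longer passed at an adjusted p of 0.01 over the list. All 16 were values of shared sites, and of the named shared sites only position 115919694 of chromosome 11 passed for both marks. Planned comparisons with genomic features, sequence context, the floxed libraries and random genome CpGs were not run.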

Other observations

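All tests in this part were chosen after the result, or a value close to it, had been seen, except the share of 5fC sites with an upper limit below 30%. That share itself had not been seen, but its 30% was the difference of medians already observed. The test was therefore also set after values of these lists had been seen.

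The first pattern is the excess of small p-values on both lists. Sampling noise at every listed site is argued against by the 2440 5fC sites below 0.01, where 1451 ± 22.9 were expected, and by the 1737 5caC sites, where 1011 ± 17.8 were expected. Copied reads or uneven conversion could also widen the spread; where they are unrelated between the 2 pairs of libraries, sites shared with the other mark would have no surplus of small p. Among the shared 5fC sites 163 had p below 0.01, against 110 ± 8.18 when the shared label was permuted within deciles of depth (permutation p = 1e-05, one-sided, the smallest that 100000 draws can give). That argues against such unrelated causes for the whole excess, but only through the 314 shared sites. The 6899 other 5fC sites had 2277 below 0.01 against 1386 expected with equal levels, and for their excess unrelated causes stay open. Copying or uneven conversion tied to a sequence, which could recur in both pairs, stays open and untested. Single sites with p near 0.05 may still be noise.

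The second pattern is the higher bisulfite-only level on the 5fC list. Read depth does not account for it over the list, as the difference averaged 29.4 percentage points (28.7 to 31.1) within 7 classes of depth, but in the class over 200 reads it was -3.12 points (-10.8 to 53.9), which leaves those sites undecided. Different cytosines on the lists stay open as the cause: the 8.33 points (6.38 to 10.0) at shared cytosines lie above the 2.40 (0.849 to 3.87) that the listing rule gives at equal levels taken from bisulfite-only reads, but overlap the 7.32 (6.26 to 8.33) at levels taken from all reads. Levels from all reads include protected reads, so they assume no rise at any shared cytosine. The 153 shared sites with a 5caC p below 0.01, against 67.2 expected by Fisher's exact test at equal levels, argue against that assumption at every site. The 7.32 is therefore an upper bound, and which level below it holds is not known. Library-wide incomplete conversion stays open. An upper limit below 30% was found at 4.44% of 5fC sites, between limits of 2.5% and 5% set for this share (a range added after this value was seen). Those limits ignore that the listing rule favours low bisulfite-only counts, so the share cannot decide. Given the listing rule, a 30% rate would put the paired difference at 10.6 points (9.75 to 11.7). Resistance of 5fC itself to bisulfite stays open too, with 4.26% of 5fC sites showing no unconverted read, as does a higher content of 5mC or 5hmC at 5fC cytosines, which these lists do not test.

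The third pattern is that 5fC and 5caC fell on the same cytosine 6.04 times as often as on partner cytosines of the same CpG. Noise at every shared cytosine is argued against by 153 shared sites with a 5caC p below 0.01, where 67.2 ± 5.49 were expected (this test replaced an earlier one whose bound depended on assumed read totals). Enrichment of the same regions with enough reads on both strands would list partner cytosines about as often as the same cytosine, yet 52 were listed against 314. At the mean chance of 5caC sites, noise alone would list 136 of 7213 cytosines if all had enough 5caC reads. The 52 partners are fewer, so many partners may have lacked these reads. Unequal read depth of the 2 strands cannot be told apart from a strand-specific placement of both marks, because reads at unlisted partners are not in the lists. Placement of both marks on the same strand of a CpG is therefore a hypothesis, untested here.

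Shared cytosines had nearly the same median 5fC level as the rest of the list, 40.9 against 40.5 points, but lower unconverted percentages. Their median bisulfite-only level was 23.1%, against 41.7% at the 6899 other 5fC sites, and their protected level was 66.7% against 86.7%. On the 5caC list the shared sites were close to the rest, with medians of 12.5% against 10.0% and 57.7% against 58.3%. Median depth was higher at the shared sites, at 25 against 19 protected reads for 5fC and 27 against 19.5 for 5caC.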
